A study of Rattus norvegicus with 12 samples.

How the data were processed

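Left ventricles of male Sprague-Dawley rats were measured on 12 one-colour (Cy3) Agilent arrays, 3 in each of 4 groups, and the labels give 1 animal per array with no pooling stated. Per the labels, all rats ate a 60% fructose diet for 8 weeks, with 0.64% NaCl (normal sodium) or below 0.01% NaCl (low sodium), and were infused subcutaneously or not with angiotensin II (AngII) at 200 ng/kg/min for the last 4 weeks. The groups are called normal sodium, normal sodium with AngII, low sodium and low sodium with AngII. Replicate numbers are those of the sample titles.

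Per the file headers, the scanner values are signal intensities from Agilent Feature Extraction 10.7.3.1, background-subtracted and detrended within each array and with no scaling between arrays. The submitters' processing notes instead name Feature Extraction 11.0.1.1, with R 3.3.04 and limma. The deposited files also hold the median pixel intensity of each spot and of its local background, and other columns with 0 or 1 flags for spots well above background, saturated, non-uniform or outlying. The authors' own matrix holds log2 values for 20438 probes, normalised between arrays by a method that is not stated. Each of its columns followed the scanner signal of its own array (Spearman's rho across probes 0.996 to 0.999, probes not being independent), and 19971 of the probes tested here are in it.

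Outlier-flagged spots (296 to 421 per array) and 1377 control spots were left out. The 42877 remaining spots hold 30367 probes, of which 1390 were printed 10 times and averaged. The log2 of the processed signal was reduced by the 75th percentile of its array. A probe was tested when it was well above background, in at least 0.5 of its spots, on all 3 arrays of at least 1 group, which left 20020 probes. Target identifiers in the files were matched to gene symbols through a RefSeq gene file (assembly GRCr8, used for names only), and 18758 probes of the array got 1 symbol, none got several and 11609 got none. Of the tested probes, 13280 carried a symbol, for 11211 genes, and 6740 did not. A gene was valued by its brightest tested probe.

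Linear models were fitted with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), with 1 mean per group over all 12 arrays, moderated variances (2.61 prior degrees of freedom) and Benjamini-Hochberg adjustment over the probes tested at 0.05. The contrasts were the AngII effect on each diet, the low sodium effect with and without AngII, the mean of each effect over the other factor, and the interaction (the AngII effect on low sodium minus that on normal sodium). Errors given with ± are limma standard errors (3 arrays per group).

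There were 34 gene lists, written from textbook knowledge before the data were examined, as were the contrasts, the alternatives and the rule for naming genes. They hold 679 entries for 667 genes, of which 631 had a probe and 579 were tested. They cover cardiac stress and fetal genes, adult contractile and calcium handling genes, collagens and matrix proteins, matrix proteases and inhibitors, TGF-beta and profibrotic signalling, and markers of smooth muscle, fibroblasts, endothelium, macrophages, lymphocytes, neutrophils and red cells, adipocytes, atria, skeletal muscle and nerve. The others are chemokines, the interferon response, MHC class II, the renin-angiotensin system, corticosteroid-responsive genes, natriuretic peptides, NADPH oxidase and antioxidant genes, fatty acid oxidation, glycolysis, fructose use and lipogenesis, cholesterol synthesis, oxidative phosphorylation, ion transport, the circadian clock, immediate early genes, hypoxia, heat shock, apoptosis and proliferation. Each list was tested two-sided with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists of a contrast, and again with the correlation estimated for each list. Members were also counted with p adjusted over the list alone.

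Named genes followed a fixed rule. Where no gene passed, the 3 with the smallest p in each direction were named as values. A list gave up to 4 members past the threshold over all genes, and a list that passed with none gave its 2 members with the smallest p. Further, 13 genes (Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1, Col3a1, Postn, Ccn2, Tgfb1, Timp1, Agtr1a and Ace) could be quoted in every contrast. Automatic symbols were passed over, and any gene named outside the rule is said to have been chosen after its values were seen. Some single-gene results are not reported here.

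The headers show 3 slides. Each slide held 1 array of every group under the same replicate number, so slide and replicate number are one factor, and each group always lay at the same position on its slide, so that position and group cannot be told apart. Correlation between same-numbered arrays, after removing group means, was above 0.1 in 17 of 18 pairs (0.333 to 0.432 for number 1, 0.119 to 0.307 for number 2 and 0.0469 to 0.229 for number 3), against a median of -0.181 over 36 pairs of different numbers. With group means removed, positive correlation within numbers forces negative correlation between numbers, so this median is no independent baseline. The consensus correlation between arrays of a slide, estimated with limma, was 0.0288. The labels do not say that numbers pair animals. Slide values beside a list are its mean log2 change within slides 1, 2 and 3, in that order. Fits with the replicate number as a block stand beside the unblocked ones. In this balanced layout blocking changes errors and p, not log2 changes.

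The alternatives were normexp background correction (offset 50, on median spot and background intensities, as the files hold no mean signal), quantile normalisation, scaling to the median, the authors' log2 values, no filter on dim probes, only probes above background on all arrays, the replicate block, a random slide block, a variance trend with robust eBayes, array weights, only the arrays of the groups compared, each array left out in turn, an estimated inter-gene correlation, and the mean of a gene's probes. Leaving out each slide, and the exact permutation of list scores (400 assignments of arrays within strata, or 64 with arrays exchanged only within slides), were added after the list results had been seen. For the interaction AngII labels were exchanged within each diet, which is exact only if AngII has no effect on either diet. An AngII effect shared by both diets widens that spread of assignments. A large p there does not show that an interaction is absent. Counts were also compared with those from other splits of the arrays, and, added later, from splits within slides.

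The fits were tested on simulated data of 19960 probes with the probe means and residual SDs of these arrays and noise independent between probes. For the AngII effect on normal sodium, 20.9% of probes changed 1.5-fold were recovered, 50.8% of those changed 2-fold and 97.0% of those changed 4-fold, with 9 false calls. For the mean low sodium effect the shares were 47.8%, 76.1% and 95.5%, with 7 false calls. A list shifted by -0.4 in that contrast, among 11167 genes, was the only 1 of 34 to pass. As the noise was independent, this cannot show list calls that arise from correlation between genes. Spots were well above background on 70.2% to 81.0% of each array, and 3 arrays per group limit the precision of every value.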

Results

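Left ventricular gene expression was compared between rats fed a high-fructose diet, a model of metabolic syndrome, with normal or low sodium and with or without AngII infusion. Each of the 4 groups had 3 arrays. The 75th percentile of the signal lay between 1399 and 1988 intensity units per array and the local background between 20 and 29.5, with no saturated spots. Arrays of the same group correlated at Pearson's r of 0.980 to 0.992 across probes, and arrays of different groups at 0.977 to 0.993 (genes are not independent replicates). The normal sodium array of replicate 1 had 88 non-uniform spots against 0 to 3 on the others, and the lowest array weight (0.279).

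The comparison of infused with uninfused rats on normal sodium asked what AngII does to the ventricle when salt is not restricted. Collagens and matrix proteins rose together: 29 of 33 measured genes were above 0, with a mean log2 change of 0.36 (adjusted p = 9.67e-08, and adjusted p = 0.553 with an estimated correlation). The slides gave 0.44, 0.41 and 0.23 in turn. Of the matrix genes 2 rose adjusted over the list alone, against 0 adjusted over all genes: Col3a1, a fibrillar collagen, was 1.39-fold higher (log2 0.48 ± 0.12, n = 3 per group) and Postn, a matricellular protein of activated fibroblasts, 1.95-fold higher (log2 0.96 ± 0.21). Postn was dim, well above background on 1 of 3 normal sodium arrays, and its log2 change was 0.39 in the authors' values and 0.32 after normexp. Smooth muscle and myofibroblast markers rose, all 12 above 0, by 0.56 on average (adjusted p = 0.000304, and adjusted p = 0.7504 with an estimated correlation). Slide means were 1.06, 0.36 and 0.28. Alpha smooth muscle actin (Acta2) stood at 0.61, and the list mean was 0.32 without slide 1. The list score was -0.33 on normal sodium and 0.23 on normal sodium with AngII. On low sodium without and with AngII it was 0.06 and 0.04. This rise, the diet shift of the list without AngII and its interaction, given below, rest on the same 3 normal sodium arrays. The list member Lmod1 stood at 1.74, but at 0.24 after normexp, 0.12 in the authors' values and 0.95 as the mean of its probes.

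Cardiac stress and fetal genes also rose on normal sodium, all 12 above 0 and 0.54 on average (adjusted p = 0.00129, and adjusted p = 0.7504 with an estimated correlation). The slides gave 0.94, 0.12 and 0.55 in turn. Among them the natriuretic peptide genes Nppb and Nppa had log2 changes of 0.81 ± 0.35 and 0.99 ± 0.82, neither past its own test, and the sarcomeric gene Myot 1.08. These hang on single arrays: Nppa was 0.06 and Nppb 0.53 without normal sodium replicate 3, Nppa 1.55 without normal sodium replicate 2 and 1.65 with array weights, Nppb 0.51 without normal sodium with AngII replicate 2, and Myot 0.72 without normal sodium replicate 1. Interferon response genes rose, with 19 of 22 above 0 and a mean of 0.46 (adjusted p = 0.000188, and adjusted p = 0.7504 with an estimated correlation). Slide means were -0.02, 1.02 and 0.33. Their examples are Irf7, a transcription factor of the type I response, at 1.05 ± 0.29 and the RNA sensor Ifih1 at 0.69 (0.36 after normexp and 0.42 in the authors' values). Proliferation genes rose, with 22 of 23 above 0 and a mean of 0.39 (adjusted p = 0.0101, and adjusted p = 0.856 with an estimated correlation). The slides gave 0.15, 0.34 and 0.70 in turn. The mitotic ubiquitin-conjugating enzyme gene Ube2c stood at 0.97, at 0.57 after normexp, at 0.61 in the authors' values and at 0.47 without normal sodium with AngII replicate 3. In these 3 lists 0 members passed adjusted over the list alone, and 0 smooth muscle markers (2 with the slide as a block). The cardiac stress call ended without normal sodium replicate 3 (0.41, adjusted p = 0.0977) or without slide 1 (0.33), and the interferon call without normal sodium replicate 2 (0.24, adjusted p = 0.103) or without slide 2 (0.16). The proliferation call ended without normal sodium replicate 1 (0.32) or 2 (0.25), without normal sodium with AngII replicate 3 (0.02), without slide 3 (0.24), with array weights (0.22) and in the authors' values (0.18), and the mean moved to 0.61 without normal sodium replicate 3, to 0.59 without normal sodium with AngII replicate 1 and to 0.20 after normexp.

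By single genes limma called 0 of 20020 probes with AngII on normal sodium. At an unadjusted p under 0.05 there were 1453 (849 higher, 604 lower), and with the slide as a block 1689, again with 0 after adjustment. About 1001 would be expected on average if no probe changed, but another split of the same arrays gave 2043. The smallest adjusted p, 0.0565, belonged to Plcd4, a phospholipase C isoform that was 2.50-fold lower (log2 -1.32 ± 0.15); its adjusted p was 0.0187 to 0.326 over 24 alternatives, of which 8 passed. Next came the tubulin gene Tuba3b at 1.16 ± 0.17, the beta-globin gene Hbb-b1 at 0.95 ± 0.15 and Rnls (renalase) at 0.75 ± 0.12 among higher values, and Rep15 at -0.85 ± 0.17 (-0.51 after normexp) and the cell cycle inhibitor gene Cdkn1c at -0.52 ± 0.11 among lower ones. The log2 changes of Col1a1, Tgfb1, Acta1, Ace and Ccn2 were 0.54, 0.46, 0.53, 0.42 and 0.37, and those of Myh7, Agtr1a, Timp1 and Myh6 were 0.04, -0.11, -0.15 and -0.20. Ccn2 turned to -0.10 without normal sodium with AngII replicate 2, and was 0.85 without replicate 3 of that group, 0.65 without normal sodium replicate 2 and 0.19 without normal sodium replicate 3. Acta1 was 0.18 without normal sodium replicate 1, 0.82 without normal sodium replicate 2 and 0.35 with array weights, Tgfb1 0.30 without normal sodium with AngII replicate 2, and Ace 0.18 after normexp and 0.26 in the authors' values. Each of the 5 list calls was kept with the slide as a block (largest adjusted p 0.00308).

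The same contrast on low sodium asked what AngII does when salt is restricted. Fatty acid oxidation genes fell: 30 of 32 were below 0, with a mean log2 change of -0.23 (adjusted p = 9.06e-10, and adjusted p = 0.0678 with an estimated correlation). Slide means were -0.13, -0.32 and -0.25. Hadhb, the beta subunit of the mitochondrial trifunctional protein, stood at -0.38 ± 0.10 and the dienoyl-CoA isomerase gene Ech1 at -0.29. This call was kept without any 1 array or slide. The list score was 0.16 on low sodium and -0.08 on low sodium with AngII. On normal sodium without and with AngII it was -0.03 and -0.05. The rise of this list on low sodium without AngII and its interaction, given below, rest on the same 3 low sodium arrays. Interferon response genes fell on this diet, with 21 of 22 below 0 and a mean of -0.35 (adjusted p = 1.35e-06, and adjusted p = 0.710 with an estimated correlation). The slides gave -0.59, -0.86 and 0.45 in turn. Irf7 stood at -0.67 (-1.02 without low sodium replicate 3) and the deconjugating protease Usp18 at -0.69. The interferon call ended without low sodium replicate 2 (-0.16), without low sodium with AngII replicate 1 (-0.29) and without slides 1 (-0.21) or 2 (-0.07), and moved to -0.60 without low sodium replicate 3 and to -0.55 with array weights.

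Matrix genes rose less far on low sodium in the mean over 33 genes, 0.12, with 25 above 0 (adjusted p = 0.000438, and adjusted p = 0.564 with an estimated correlation). Slide means were 0.29, 0.07 and -0.01. The test of the difference between diets is given with the interaction. The proteoglycan gene Bgn stood at 0.37 and Col18a1 at 0.49 (0.25 with array weights), but Col3a1 at 0.02 and Postn at -0.12. The matrix call ended without low sodium replicate 1 (0.09) or without slide 1 (0.03), and the mean was 0.05 without low sodium with AngII replicate 1. Proliferation genes rose, with 19 of 23 above 0 and a mean of 0.20 (adjusted p = 0.0101, and adjusted p = 0.784 with an estimated correlation), cyclin D1 (Ccnd1) standing at 0.45, and at 0.21 without low sodium replicate 1. The slides gave 0.42, -0.20 and 0.39 in turn. Heat shock and unfolded protein response genes fell, with 18 of 19 below 0 and a mean of -0.15 (adjusted p = 0.0125, and adjusted p = 0.564 with an estimated correlation), with Trib3 at -0.58 (-0.38 after normexp) and Herpud1 at -0.19. Slide means were -0.19, -0.17 and -0.09. The proliferation call ended without low sodium replicate 1 (0.12) or 3 (0.15), low sodium with AngII replicate 3 (0.16), slide 1 (0.09), slide 3 (0.11) or the filter on dim probes (0.18), and the mean was 0.33 without low sodium replicate 2. The heat shock call ended without low sodium replicate 1 (-0.11) or 2 (-0.17), low sodium with AngII replicate 1 (-0.18) or 2 (-0.12), slide 1 (-0.13) or slide 2 (-0.14).

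No member of these 5 lists passed when adjusted over the list alone, and limma called 0 probes for AngII on low sodium. At an unadjusted p under 0.05 there were 342 (176 higher, 166 lower), below the 1001 expected on average if no probe changed. With the block there were 460, 0 of them after adjustment. The genes with the smallest p (adjusted p = 1.00 each) were Prelid2 at 0.83 ± 0.14, Ccdc157 at 0.69 and Epn3 at 1.28 upward, and Arl5c at -0.88 and Ncf1, the p47phox subunit of NADPH oxidase, at -0.74 downward. With the mean of a gene's probes Prelid2 was 0.43 and Epn3 0.77, and Arl5c was -0.32 after normexp and -0.51 in the authors' values. Grid1 was well above background on no low sodium with AngII array. Its fall was at least 1.43-fold in the processed signal, but its log2 change was only -0.13 after normexp. Nppa stood at 0.85 ± 0.82, Acta1 at 0.43, Ace at 0.23, Nppb at 0.20, Col1a1 at 0.12, Timp1 at 0.08, Ccn2 at 0.05, Myh7 at -0.04 and Tgfb1 at -0.19. Without low sodium with AngII replicate 1 Nppa was 0.16 and Acta1 0.20, and Nppa was 0.39 without low sodium replicate 3 and 1.46 without low sodium with AngII replicate 3. Each of the 5 list calls was kept with the slide as a block (largest adjusted p 0.0120).

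The diet contrast without infusion asked what salt restriction alone does in fructose-fed rats. Collagens and matrix proteins fell: 29 of 33 were below 0, with a mean log2 change of -0.28 (adjusted p = 1.72e-08, and adjusted p = 0.426 with an estimated correlation). The slides gave -0.32, -0.14 and -0.37 in turn. Adjusted over the list alone 7 members fell, and 0 with the slide as a block, against 0 over all genes; they include Col14a1 (-0.60) and, chosen after their values were seen, Col8a1 (-0.72), the elastic fibre gene Fbln5 (-0.65) and the crosslinking enzyme gene Loxl2 (-0.54). Col3a1 stood at -0.42 ± 0.12 and at -0.25 after normexp. Macrophage and monocyte markers fell, with 16 of 19 below 0 and a mean of -0.31 (adjusted p = 0.000396, and adjusted p = 0.495 with an estimated correlation). Slide means were 0.07, -0.67 and -0.32. Adjusted over this list alone 2 members fell, Adgre1 (F4/80), 1.93-fold lower at -0.95 ± 0.15, and the lipid receptor gene Trem2 at -1.02 ± 0.22 (3 with the block). The macrophage call ended without low sodium replicate 2 (-0.13), normal sodium replicate 3 (-0.23) or slide 2 (-0.13).

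Endothelial markers fell too, with 12 of 14 below 0 and a mean of -0.28 (adjusted p = 0.00288, and adjusted p = 0.506 with an estimated correlation), VE-cadherin (Cdh5) standing at -0.35 (-0.15 after normexp and in the authors' values) and Emcn at -0.30. The slides gave -0.72, 0.07 and -0.21 in turn. Proliferation genes fell, with 22 of 23 below 0 and a mean of -0.46 (adjusted p = 0.000229, and adjusted p = 0.506 with an estimated correlation), among them Ccnd1 at -0.78 and cyclin B1 (Ccnb1) at -0.76. Slide means were -0.47, 0.08 and -1.0. Fatty acid oxidation genes rose, with 28 of 32 above 0 and a mean of 0.19 (adjusted p = 0.000396, and adjusted p = 0.426 with an estimated correlation), where lipoprotein lipase (Lpl) stood at 0.65 and Eci1 at 0.34. The slides gave 0.15, 0.28 and 0.12 in turn. Oxidative phosphorylation genes rose by 0.09 on average, 25 of 38 above 0 (adjusted p = 0.00696, and adjusted p = 0.506 with an estimated correlation), with Ndufs1 of complex I at 0.36, and at 0.16 without normal sodium replicate 1. Slide means were 0.07, 0.11 and 0.09. Interferon response genes rose by 0.29 on average, 15 of 22 above 0 (adjusted p = 0.0135, and adjusted p = 0.528 with an estimated correlation), Irf7 standing at 1.01 and Oasl at 1.26 ± 0.68. Oasl was 0.19 after normexp, 0.47 in the authors' values, 0.44 without normal sodium replicate 2, 0.73 without low sodium replicate 2 and 2.00 without normal sodium replicate 1. The slides gave -0.05, 1.09 and -0.17 in turn. Without slide 2 this interferon mean was -0.12, the opposite sign.

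In the uninfused diet contrast the endothelial call ended without low sodium replicate 1 (-0.17), normal sodium replicate 3 (-0.25) or slide 1 (-0.07), the mean being -0.18 without normal sodium replicate 1, and the proliferation call ended without normal sodium replicate 3 (-0.24), the mean being -0.19 without slide 3. The interferon call ended without low sodium replicate 1 (0.23) or 2 (0.11), or normal sodium replicate 2 (0.07) or 3 (0.28), and its mean was 0.55 without low sodium replicate 3, 0.52 without normal sodium replicate 1 and 0.50 with array weights. The oxidative phosphorylation call ended without low sodium replicate 2 (0.05), normal sodium replicate 3 (0.05) or slide 2 (0.08) and in the authors' values (0.08), and the fatty acid oxidation call without slide 2 (0.14). No member of these 5 lists passed when adjusted over the list alone, and limma called 0 probes. At an unadjusted p under 0.05 there were 1407 (575 higher, 832 lower), and 1703 with the block, 0 of them after adjustment. The smallest adjusted p was 0.508, shared by Nacad at 1.61 ± 0.30 (1.05 after normexp), Usp28 at 0.60, Cxcl12 at 0.59 (another of its probes -0.19, their mean 0.20), Adgre1, Prr7 at -0.98 and the carbonic anhydrase gene Car4 at -0.97. Nppa stood at -1.71 ± 0.82, Nppb at -0.83 ± 0.35, Timp1 at -0.54, Ccn2 at -0.30, Postn at -0.28, Acta1 at -0.27, Myh6 at -0.26, Tgfb1 at -0.25, Col1a1 at -0.19, Ace at -0.18, Myh7 at -0.15 and Agtr1a at -0.08. Nppa was -2.65 without normal sodium replicate 3 and -0.92 with array weights, and Nppb -0.44 without normal sodium replicate 2. Each of the 7 list calls was kept with the slide as a block (largest adjusted p 0.0152), which called 9 lists, adding smooth muscle markers (0.40 on average) and the natriuretic peptide system (-0.36), both at adjusted p = 0.0297 against 0.0590 and 0.0821 without it. With the block and an estimated correlation 0 lists passed, these 2 at adjusted p = 0.542 and 0.531.

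With AngII infusion in both groups, the diet contrast asked whether salt restriction changes the ventricle under this pressor hormone. Collagens and matrix proteins fell: 31 of 33 were below 0 on low sodium, with a mean log2 change of -0.52 (adjusted p = 1.03e-12, and adjusted p = 0.159 with an estimated correlation). Slide means were -0.47, -0.48 and -0.60. Of the matrix genes 16 fell adjusted over the list alone, also 16 with the block, against 0 over all genes: Col3a1 was 1.85-fold lower (log2 -0.88 ± 0.12), Postn stood at -1.36 ± 0.21 and, chosen after its value was seen, Col8a1 at -1.25. For the dim Postn the change was -0.23 in the authors' values and -0.47 after normexp. Cardiac stress and fetal genes fell, with 11 of 12 below 0 and a mean of -0.69 (adjusted p = 0.000805, and adjusted p = 0.528 with an estimated correlation). The slides gave -0.53, -0.92 and -0.64 in turn. The list score was 0.50 on normal sodium with AngII and -0.03 on normal sodium. On low sodium without and with AngII it was -0.28 and -0.19. This fall, the rise with AngII on normal sodium and the interaction of the list share the same 3 normal sodium with AngII arrays. Adjusted over this list alone 2 members fell, Nppb, 2.71-fold lower at -1.44 ± 0.35, and the TWEAK receptor gene Tnfrsf12a at -1.14.

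Markers of other cell types fell with the matrix genes in infused rats on low sodium. Macrophage and monocyte markers were below 0 for 18 of 19 genes, with a mean of -0.40 (adjusted p = 0.000109, and adjusted p = 0.528 with an estimated correlation). Slide means were -0.36, -0.33 and -0.52. Adjusted over the list alone 4 of them fell (5 with the block): Adgre1 (-0.67), Aif1 (-0.54) and, chosen after their values were seen, the Fc receptor gene Fcgr1a (-0.72) and the lysosomal marker Cd68 (-0.58). Endothelial markers were below 0 for all 14 genes, with a mean of -0.38 (adjusted p = 0.000218, and adjusted p = 0.528 with an estimated correlation), and 1 fell adjusted over the list alone, the apelin receptor gene Aplnr, 2.29-fold lower. The slides gave -0.20, -0.43 and -0.49 in turn. Interferon response genes fell, with 20 of 22 below 0 and a mean of -0.52 (adjusted p = 6.19e-05, and adjusted p = 0.592 with an estimated correlation). Slide means were -0.62, -0.79 and -0.05. Examples are Gbp2 at -0.69 and the immunoproteasome gene Psmb8 at -0.66. Proliferation genes fell, with 22 of 23 below 0 and a mean of -0.65 (adjusted p = 6.19e-05, and adjusted p = 0.592 with an estimated correlation), Ccnb1 standing at -0.94, at -0.57 after normexp, at -0.48 in the authors' values and at -0.52 without normal sodium with AngII replicate 3. The slides gave -0.20, -0.46 and -1.31 in turn. The proliferation mean was -0.28 without normal sodium with AngII replicate 3, which ended the call, -0.33 without slide 3 and -0.38 in the authors' values, and the interferon call ended without slide 1 (-0.42).

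Smaller list shifts with infusion were NADPH oxidase and antioxidant genes, which fell by 0.31 on average with 18 of 22 below 0 (adjusted p = 0.0180, and adjusted p = 0.329 with an estimated correlation), heme oxygenase 1 (Hmox1) standing at -1.23 and the oxidase subunit gene Cybb at -0.75 (-0.35 after normexp and -0.21 in the authors' values). Slide means were -0.33, -0.35 and -0.26. Matrix proteases and inhibitors fell by 0.26 on average with 13 of 15 below 0 (adjusted p = 0.0439, and adjusted p = 0.329 with an estimated correlation), with Timp3 at -0.64 and Adamts5 at -0.51. The slides gave -0.20, -0.34 and -0.25 in turn. Cholesterol synthesis genes rose by 0.16 on average with 17 of 20 above 0 (adjusted p = 0.0177, and adjusted p = 0.697 with an estimated correlation), Msmo1 standing at 0.47, and at 0.25 without normal sodium with AngII replicate 2. Slide means were 0.29, 0.31 and -0.12. Oxidative phosphorylation genes rose by 0.06 with 30 of 38 above 0 (adjusted p = 0.0180, and adjusted p = 0.697 with an estimated correlation), with Ndufb3 at 0.26. The slides gave 0.14, 0.12 and -0.09 in turn. Adjusted over the list alone 0 members of these 4 lists, of the interferon list and of the proliferation list passed. The protease call was the only 1 of 10 lost with the slide as a block (adjusted p = 0.0563, and 0.0155 at most for the other 9). It was also lost without low sodium replicate 3 (adjusted p = 0.0550), low sodium with AngII replicate 1 (0.144) or 2 (0.0516), normal sodium replicate 3 (0.05001), normal sodium with AngII replicate 1 (0.0961) or 3 (0.0687), slide 1 (0.227), the filter on dim probes (0.0677), dim probes altogether (0.0787) and with the mean of a gene's probes (0.0622), and its mean was -0.16 after scaling to the median. Over the fits without 1 array the protease mean was -0.32 to -0.22, so the shift itself was kept there. The NADPH call ended without low sodium with AngII replicate 1 (-0.32), normal sodium with AngII replicate 1 (-0.30) or slide 1 (-0.30). The cholesterol call ended without normal sodium with AngII replicate 1 (0.11) or 2 (0.07), slides 1 (0.09) or 2 (0.09) and in the authors' values (0.14), and its mean was 0.30 without normal sodium with AngII replicate 3 and 0.26 after scaling to the median. The oxidative phosphorylation call ended without low sodium with AngII replicate 1 (0.02) or 2 (0.04), normal sodium with AngII replicate 1 (0.05), slides 1 (0.02) or 2 (0.03), after quantile normalisation (0.03) and in the authors' values (0.02), and its mean was 0.11 without low sodium with AngII replicate 3 and 0.16 after scaling to the median.

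By single genes limma called 0 probes between diets with infusion. At an unadjusted p under 0.05 there were 2223 (740 higher, 1483 lower), and 2339 with the block, 0 of them after adjustment. Plcd4 was 2.59-fold higher on low sodium (log2 1.37 ± 0.15; adjusted p = 0.0567, and 0.0128 to 0.298 over 24 alternatives, of which 10 passed). Col3a1 came next (adjusted p = 0.0790, and 0.0128 to 0.338 over 24 alternatives, of which 2 passed), then Cdkn1c at 0.74, Tm7sf2 of cholesterol synthesis at 0.79 (0.46 after normexp), Postn, and the creatine synthesis gene Gatm at -0.79 (another of its probes -0.28). Nppa stood at -1.85 ± 0.82, Tgfb1 at -0.90, Ccn2 at -0.62, Col1a1 at -0.60, Ace at -0.37, Acta1 at -0.37, Timp1 at -0.31, Myh7 at -0.23, Myh6 at -0.06 and Agtr1a at 0.03. Without normal sodium with AngII replicate 2 Ccn2 was -0.14, and without replicate 3 of that group it was -1.10. Without low sodium with AngII replicate 1 Ace was -0.61 and Acta1 -0.60, and without replicate 3 of that group Ace was -0.19, Acta1 -0.23 and Timp1 -0.16. Acta1 was also -0.23 without normal sodium with AngII replicate 3, and Timp1 was -0.20 without normal sodium with AngII replicate 1 and after scaling to the median. The median log2 change of all probes was -0.05 here, and 0.05 after scaling to the median, so list shifts near this size are relative to the scaling.

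The mean AngII effect over both diets asked what the infusion does irrespective of salt. Collagens and matrix proteins rose, with 31 of 33 above 0 and a mean log2 change of 0.24 (adjusted p = 3.60e-13, and adjusted p = 0.144 with an estimated correlation). Slide means were 0.37, 0.24 and 0.11. The elastic fibre gene Mfap4 stood at 0.39 and Col18a1 at 0.50. Fatty acid oxidation genes fell, with 25 of 32 below 0 and a mean of -0.13 (adjusted p = 0.000345, and adjusted p = 0.256 with an estimated correlation), including Acsl1 at -0.28 and Hadhb at -0.23. The slides gave -0.03, -0.18 and -0.16 in turn. Heat shock and unfolded protein response genes fell, with 17 of 19 below 0 and a mean of -0.12 (adjusted p = 0.00116, and adjusted p = 0.256 with an estimated correlation), with Xbp1 at -0.28. Slide means were -0.13, -0.19 and -0.03. Cardiac stress genes rose, with 10 of 12 above 0 and a mean of 0.31 (adjusted p = 0.00181, and adjusted p = 0.392 with an estimated correlation). The slides gave 0.72, -0.07 and 0.28 in turn. Smooth muscle markers rose, with 10 of 12 above 0 and a mean of 0.27 (adjusted p = 0.000829, and adjusted p = 0.392 with an estimated correlation), Mcam standing at 0.22. Slide means were 0.61, -0.10 and 0.30. Lmod1 of this list stood at 0.76, but at 0.13 after normexp and 0.04 in the authors' values. Proliferation genes rose, with 22 of 23 above 0 and a mean of 0.30 (adjusted p = 3.03e-05, and adjusted p = 0.495 with an estimated correlation), the cytokinesis gene Prc1 standing at 0.62, at 0.37 with array weights and at 0.34 without normal sodium with AngII replicate 3. The slides gave 0.28, 0.07 and 0.54 in turn. MHC class II genes fell, with 7 of 8 below 0 and a mean of -0.42 (adjusted p = 0.0281, and adjusted p = 0.392 with an estimated correlation). Slide means were -1.10, 0.09 and -0.24. Neutrophil and red cell markers rose by 0.17, with 5 of 8 above 0 (adjusted p = 0.0338, and adjusted p = 0.392 with an estimated correlation). The slides gave -0.36, 0.53 and 0.35 in turn. Adjusted over the list alone 2 of these rose, against 0 over all genes, the erythroid heme synthesis gene Alas2 (0.83 ± 0.18) and the globin gene Hbb (0.36 ± 0.11, and 0.57 as the mean of its probes), while 0 members of the other 7 lists passed (4 matrix genes with the block).

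Some of these effects stood further from 0 on 1 diet. On normal and low sodium the AngII effect was 0.56 and -0.02 for smooth muscle markers, -0.02 and -0.23 for fatty acid oxidation, 0.54 and 0.09 for cardiac stress genes, -0.70 and -0.13 for MHC class II and 0.28 and 0.06 for neutrophil and red cell markers. A difference between diets was not shown for the last 2 lists (interaction, exact permutation, two-sided p = 0.425 and 0.515). Tests for the others are given with the interaction. For the mean AngII effect the cardiac stress call ended without normal sodium replicate 3 (0.25), slide 1 (0.11) or slide 3 (0.33). The smooth muscle call ended without slides 1 (0.10) or 3 (0.25) and with array weights (0.15), and its mean was 0.18 without normal sodium with AngII replicate 1. The proliferation call ended without normal sodium with AngII replicate 3 (0.11) or slide 3 (0.17), and its mean was 0.19 after normexp and 0.18 with array weights. The heat shock call ended without normal sodium replicate 2 (-0.08) or slide 1 (-0.11) and in the authors' values (-0.08), and the fatty acid oxidation call without slide 2 (-0.10). The MHC class II call ended without low sodium replicate 1 (-0.37), low sodium with AngII replicate 1 (-0.39) or 3 (-0.42), normal sodium replicate 3 (-0.35), normal sodium with AngII replicate 1 (-0.18), slide 1 (-0.07) or slide 3 (-0.51), after scaling to the median (-0.44), in the authors' values (-0.18), without dim probes (-0.15) and with array weights (-0.52), and its mean was -0.27 with the mean of a gene's probes. The red cell call ended without low sodium replicates 2 (0.14) or 3 (0.08), low sodium with AngII 2 (0.12) or 3 (0.17), normal sodium 2 (0.14) or 3 (0.19), normal sodium with AngII 2 (0.12) or 3 (0.15), slide 2 (-0.00468, the opposite sign) or slide 3 (0.08), in the authors' values (0.12), without the filter on dim probes (0.09) and with array weights (0.12), and its mean was 0.30 without low sodium replicate 1. Each of the 8 list calls was kept with the slide as a block (largest adjusted p 0.0468), and the matrix call also without any 1 array or slide. By exact permutation of list scores within diet (two-sided), 3 lists had p under 0.05, matrix proteins (p = 0.015), heat shock (p = 0.035) and fatty acid oxidation (p = 0.04), and 0 after adjustment over 34 lists (smallest 0.453). Within slides 1 list had an exact p under 0.05, the natriuretic peptide system, and 0 after adjustment (smallest 0.531).

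Of single genes limma called 0 for the mean AngII effect; at an unadjusted p under 0.05 there were 576 probes (364 higher, 212 lower), and 813 with the block, 0 of them after adjustment. Upward the smallest p belonged to Ltbp2 of the TGF-beta signalling list, 1.77-fold higher at 0.82 ± 0.14. Hbb-b1 at 0.56 and Epn3 at 1.11 (0.74 as the mean of its probes) followed. Downward it belonged to Arl5c at -0.75 (-0.31 after normexp), the dim Grid1 and Plcd4 at -0.56 (limma, adjusted p = 0.868 for each gene in both directions). Nppa stood at 0.92, Nppb at 0.50, Acta1 at 0.48, Postn at 0.42, Col1a1 at 0.33, Ace at 0.33, Col3a1 at 0.25, Ccn2 at 0.21, Tgfb1 at 0.14, Timp1 at -0.04, Agtr1a at -0.06 and Myh6 at -0.10. Nppa was 0.45 without normal sodium replicate 3, and without low sodium with AngII replicate 1 Nppa was 0.57 and Ace 0.21. Acta1 was 0.31 without normal sodium replicate 1, Ace 0.20 after normexp, and Postn 0.18 after normexp, 0.26 in the authors' values and 0.28 with array weights.

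The mean diet effect over both infusion states asked what salt restriction does irrespective of AngII. Collagens and matrix proteins fell, with 29 of 33 below 0 and a mean log2 change of -0.40 (adjusted p = 3.17e-15, and adjusted p = 0.0956 with an estimated correlation). Slide means were -0.39, -0.31 and -0.49. Of these 23 fell adjusted over the list alone (24 with the block), against 0 over all genes. Col3a1 was 1.57-fold lower (log2 -0.65 ± 0.08, 6 arrays against 6) and Col8a1 1.98-fold lower, and the dim Postn stood at -0.82, at -0.33 after normexp and at -0.10 in the authors' values. The mean score of the 33 genes was 0.02 ± 0.16 on normal sodium, 0.38 ± 0.09 on normal sodium with AngII, -0.26 ± 0.06 on low sodium and -0.14 ± 0.11 on low sodium with AngII (SD, n = 3). Macrophage and monocyte markers fell, with 17 of 19 below 0 and a mean of -0.35 (adjusted p = 3.40e-06, and adjusted p = 0.379 with an estimated correlation), and 9 fell adjusted over the list alone (7 with the block), among them Adgre1, 1.75-fold lower (-0.81 ± 0.11), Aif1 (-0.47) and, chosen after their values were seen, the colony-stimulating factor receptor gene Csf1r (-0.68) and Trem2 (-0.64). The slides gave -0.14, -0.50 and -0.42 in turn. Endothelial markers fell, all 14 below 0, by 0.33 on average (adjusted p = 2.05e-05, and adjusted p = 0.379 with an estimated correlation), and 5 fell adjusted over the list alone, Aplnr (-0.83), Cdh5 (-0.40) and, chosen after their values were seen, Tie1 (-0.66), Ednrb (-0.62) and Emcn (-0.31). Slide means were -0.46, -0.18 and -0.35. Proliferation genes fell, with 22 of 23 below 0 and a mean of -0.56 (adjusted p = 5.64e-07, and adjusted p = 0.413 with an estimated correlation), and 12 fell adjusted over the list alone, Ccnb1 standing at -0.85, and at -0.54 after normexp and in the authors' values. The slides gave -0.33, -0.19 and -1.15 in turn. These 4 calls were kept without any 1 array and without any 1 slide, the proliferation mean being -0.26 without slide 3.

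**Figure D1:**
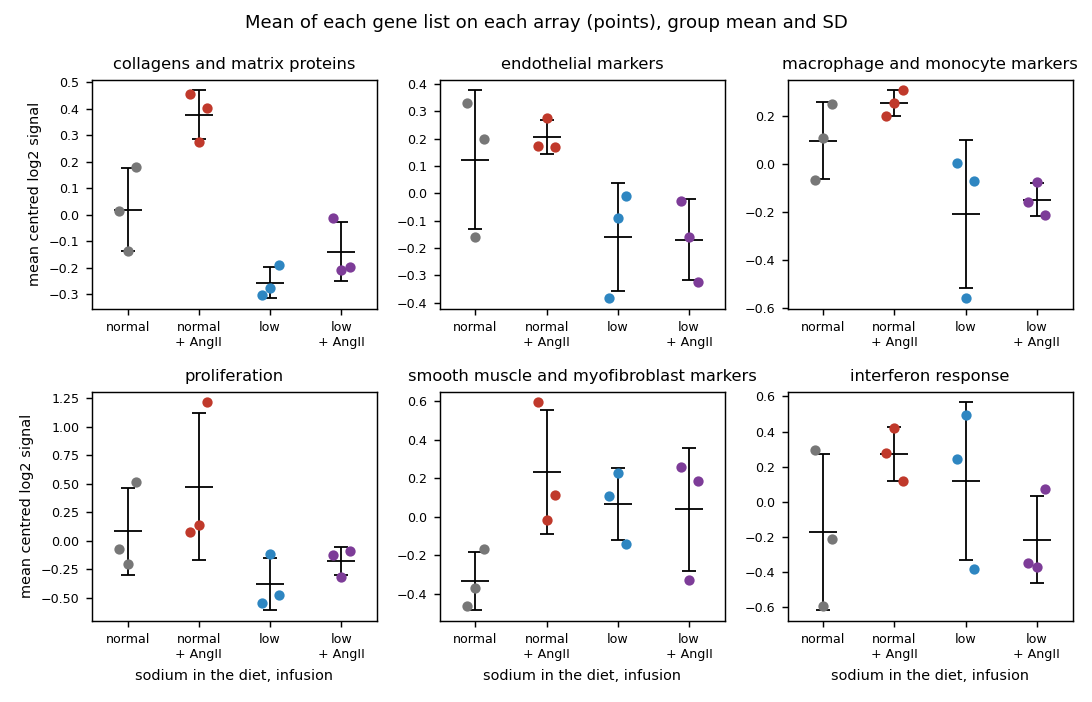
Mean centred log2 score (y axis) of 6 gene lists in the 4 groups (x axis), with 1 point per array, bars at the group mean and error bars of 1 SD (n = 3). The matrix score averaged 0.38 on normal sodium with AngII and -0.14 on low sodium with AngII.

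Cardiac stress and fetal genes fell on low sodium, with 10 of 12 below 0 and a mean of -0.47 (adjusted p = 0.0117, and adjusted p = 0.437 with an estimated correlation), and Nppb, 2.20-fold lower at -1.14, was the 1 member that fell adjusted over the list alone. Slide means were -0.30, -0.73 and -0.37. NADPH oxidase and antioxidant genes fell by 0.22, with 16 of 22 below 0 (adjusted p = 0.0483, and adjusted p = 0.379 with an estimated correlation), and 3 fell adjusted over the list alone, Hmox1 (-1.0), the oxidase subunit gene Cyba (-0.45) and, chosen after its value was seen, the oxidase gene Nox4 (-1.24). The slides gave -0.22, -0.24 and -0.21 in turn. Matrix proteases and inhibitors fell by 0.19, with 13 of 15 below 0 (adjusted p = 0.0334, and adjusted p = 0.372 with an estimated correlation). Slide means were -0.15, -0.25 and -0.16. The inhibitor gene Timp1 (-0.42) fell adjusted over the list alone, and 0 members with the block. Oxidative phosphorylation genes rose by 0.07, with 34 of 38 above 0 (adjusted p = 0.000681, and adjusted p = 0.442 with an estimated correlation), Cox7b standing at 0.24. The slides gave 0.11, 0.12 and 0.00 in turn. Glucose uptake and glycolysis genes rose by 0.09, with 17 of 24 above 0 (adjusted p = 0.0334, and adjusted p = 0.442 with an estimated correlation), with the glucose transporter gene Slc2a1 at 0.46 and Pfkm at 0.23; no member of either list passed adjusted over the list alone. Slide means were 0.13, 0.12 and 0.04. Without and with AngII the diet effect was -0.24 and -0.69 for cardiac stress genes, -0.14 and -0.31 for NADPH oxidase genes and -0.11 and -0.26 for proteases. Each of these 3 passed with AngII and not without it, which does not show a difference between infusion states. For their interaction the exact permutation gave two-sided p of 0.25, 0.025 and 0.16, each 0.85 after adjustment. The cardiac stress call ended without normal sodium replicate 2 (-0.36) or slide 2 (-0.34). The NADPH call ended without low sodium replicate 3 (-0.22), low sodium with AngII replicate 1 (-0.23), normal sodium replicate 2 (-0.22), normal sodium with AngII replicates 1 (-0.22) or 2 (-0.21), slides 1 (-0.23) or 2 (-0.22), after normexp (-0.17), without dim probes (-0.18), with array weights (-0.22) and with the mean of a gene's probes (-0.22). The protease call ended without low sodium replicate 3 (-0.18), low sodium with AngII replicate 1 (-0.21), normal sodium replicate 2 (-0.17), slides 2 (-0.16) or 3 (-0.20), after normexp (-0.15), without dim probes (-0.17) and with array weights (-0.17), and its mean was -0.11 after scaling to the median. The glycolysis call ended without low sodium replicate 3 (0.08), low sodium with AngII 1 (0.06) or 2 (0.08), normal sodium 3 (0.06), normal sodium with AngII 1 (0.07), slides 1 (0.08) or 2 (0.08), after quantile normalisation (0.07) and in the authors' values (0.06), and its mean was 0.16 after scaling to the median. The oxidative phosphorylation call ended without slide 2 (0.05) and in the authors' values (0.05), and its mean was 0.15 after scaling to the median.

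An exact permutation test of each list's score, with arrays reassigned between diets within infusion state (two-sided, 400 assignments, smallest possible p 0.005), gave 12 lists with p under 0.05 for the mean diet effect, all lower on low sodium. After adjustment over 34 lists 11 passed (adjusted p = 0.0464 each). These assignments exchange arrays across slides, although arrays of a slide were correlated. With arrays exchanged only within slides (64 assignments, smallest possible exact p 0.03125), 8 of the 11 had p under 0.05, not macrophage, endothelial and proliferation genes (exact p = 0.0625 each), and 0 of 34 lists passed after adjustment (smallest 0.118). In this exact test matrix proteins, NADPH oxidase and antioxidant genes and the renin-angiotensin system (score difference -0.17) had p = 0.005, and proteases, macrophage markers and proliferation genes p = 0.01. Endothelial markers, TGF-beta signalling (-0.17), fibroblast markers (-0.16), natriuretic peptide genes (-0.38) and adipocyte markers (-0.18) had an exact p = 0.015, whereas cardiac stress genes (p = 0.035, adjusted 0.0992) did not pass. This test does not compare a list with other genes, and for renin-angiotensin, TGF-beta, fibroblast, natriuretic peptide and adipocyte lists camera gave adjusted p of 0.143, 0.0789, 0.247, 0.0882 and 0.0924. The score of each diet's 6 arrays did not overlap for the NADPH and renin-angiotensin lists.

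By single genes limma called 0 probes for the mean diet effect. At an unadjusted p under 0.05 there were 2508 (813 higher, 1695 lower), and 2777 with the block, 0 of them after adjustment. Col3a1, Adgre1 and the transcription factor gene Mycn (2.29-fold lower, -1.19 ± 0.18) had the smallest adjusted p, 0.116 each. Over the alternatives these were 0.0281 to 0.378 for Col3a1 (3 passed), 0.0435 to 0.378 for Adgre1 (2 passed) and 0.0281 to 0.378 for Mycn (2 passed). Upward the smallest p belonged to Nacad, 2.44-fold higher at 1.29 ± 0.21, Usp28 at 0.43 and the diphosphatase gene Nudt4 at 0.56. Nppa was 3.44-fold lower at -1.78 ± 0.58 (adjusted p = 0.253), and Tgfb1 stood at -0.58, Ccn2 at -0.46, Col1a1 at -0.39, Acta1 at -0.32, Ace at -0.28, Myh7 at -0.19, Myh6 at -0.16 and Agtr1a at -0.03. Ccn2 was -0.22 without normal sodium with AngII replicate 2 and -0.70 without replicate 3 of that group, and Acta1 was -0.18 without normal sodium replicate 2 and -0.50 without normal sodium replicate 1. Each of the 9 list calls was kept with the slide as a block (largest adjusted p 0.0399), which called 10 lists, adding the natriuretic peptide system (-0.38; adjusted p = 0.0342, against 0.0882 without it). With the block and an estimated correlation 0 lists passed, this one at adjusted p = 0.306.

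**Figure D2:**
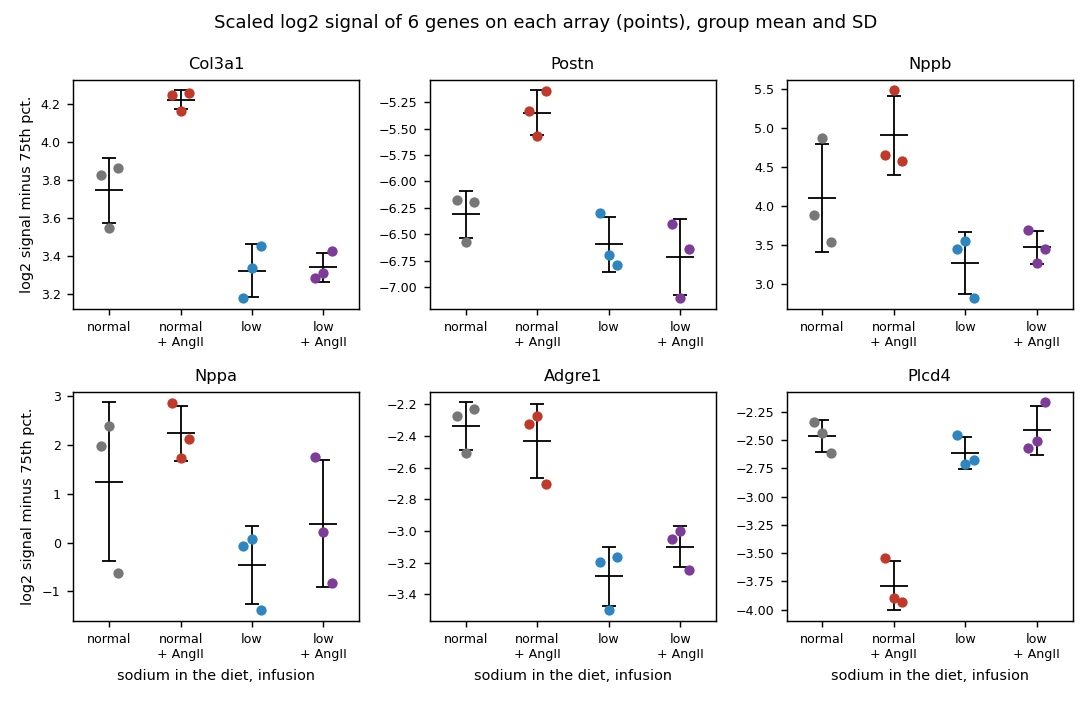
Log2 signal minus the 75th percentile of its array (y axis) for Col3a1, Postn, Nppb, Nppa, Adgre1 and Plcd4 in the 4 groups (x axis), with 1 point per array, bars at the group mean and error bars of 1 SD (n = 3). Mean Col3a1 was 4.22 on normal sodium with AngII and 3.34 on low sodium with AngII, and mean Plcd4 was -3.79 and -2.41.

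The interaction asked whether the response to AngII differs between diets, as the AngII effect on low sodium minus that on normal sodium. Interferon response genes differed, with 20 of 22 below 0 and a mean of -0.81 (adjusted p = 8.82e-08, and adjusted p = 0.886 with an estimated correlation). The slides gave -0.57, -1.88 and 0.12 in turn. Irf7 (-1.72 ± 0.41) was the 1 member lower adjusted over the list alone (0 with the block), against 0 over all genes, and Usp18 stood at -1.02. The interferon call was kept without any 1 array, and ended without slide 2 (-0.24), the mean being -1.27 without slide 3. Smooth muscle and myofibroblast markers differed by -0.59, with 11 of 12 below 0 (adjusted p = 0.0116, and adjusted p = 0.886 with an estimated correlation), Acta2 standing at -0.79. Slide means were -0.91, -0.91 and 0.05. Lmod1 of this list stood at -1.95, but at -0.22 after normexp and -0.16 in the authors' values. Fatty acid oxidation genes differed by -0.21, with 28 of 32 below 0 (adjusted p = 0.0116, and adjusted p = 0.886 with an estimated correlation), with Lpl at -0.80 and Ech1 at -0.47. The slides gave -0.19, -0.27 and -0.18 in turn. Cholesterol synthesis genes differed by 0.20, with 14 of 20 above 0 (adjusted p = 0.0286, and adjusted p = 0.886 with an estimated correlation), where Cyp51 was 0.53. Slide means were 0.00, 0.73 and -0.14. Cardiac stress genes differed by -0.45, all 12 below 0 (adjusted p = 0.0386, and adjusted p = 0.886 with an estimated correlation), including Tnfrsf12a at -1.05 and Nppb at -0.61. Nppb was -0.33 without normal sodium replicate 3, -0.32 without normal sodium with AngII replicate 2 and -0.9956 without normal sodium replicate 2. The slides gave -0.45, -0.38 and -0.52 in turn. Collagens and matrix proteins differed by -0.24, with 25 of 33 below 0 (adjusted p = 0.0484, and adjusted p = 0.886 with an estimated correlation), with Col3a1 at -0.46. Slide means were -0.15, -0.34 and -0.23.

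Of these 6 interaction calls, the smooth muscle call ended without low sodium replicate 2 (-0.51), low sodium with AngII replicate 2 (-0.41), normal sodium with AngII replicate 1 (-0.41), slide 1 (-0.43) or slide 2 (-0.43), and its mean was -0.91 without slide 3. The fatty acid oxidation call ended without low sodium replicate 2 (-0.20), normal sodium with AngII replicate 1 (-0.18), slide 1 (-0.23) or slide 2 (-0.18). The cholesterol call ended without low sodium replicate 2 (0.19), low sodium with AngII replicate 3 (0.20), normal sodium replicate 2 (0.01), normal sodium with AngII replicates 1 (0.15) or 2 (0.10) or slide 2 (-0.07, the opposite sign), after normexp (0.18) and in the authors' values (0.15), and its mean was 0.33 without normal sodium replicate 1 or normal sodium with AngII replicate 3. The cardiac stress call ended without low sodium replicate 2 (-0.37), low sodium with AngII replicates 2 (-0.36) or 3 (-0.36), normal sodium replicates 1 (-0.35) or 3 (-0.33), normal sodium with AngII replicate 1 (-0.35), slide 1 (-0.45) or slide 3 (-0.41), and its mean was -0.68 without normal sodium replicate 2. The matrix call was kept in 3 of 12 fits without 1 array and ended without low sodium 2 (-0.25) or 3 (-0.21), low sodium with AngII 1 (-0.31), 2 (-0.21) or 3 (-0.21), normal sodium 1 (-0.24) or 2 (-0.16), normal sodium with AngII 1 (-0.20) or 3 (-0.23), each slide (-0.29, -0.19 and -0.25), in the authors' values (-0.16), without dim probes (-0.18) and with array weights (-0.23), and its mean was -0.16 after normexp. Each of the 6 calls was kept with the slide as a block (largest adjusted p 0.0403). By exact permutation (two-sided) only the NADPH list had p under 0.05 (p = 0.025), and 0 lists passed after adjustment (smallest 0.850), and within slides 0 lists had an exact p under 0.05. These permutations exchange AngII labels within diets, so an AngII effect shared by both diets widens their spread. They do not decide on an interaction.

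Of single genes limma called 0 for the interaction; at an unadjusted p under 0.05 there were 1014 probes (421 higher, 593 lower), and 1138 with the block, 0 of them after adjustment. Plcd4 had the smallest p, with a difference of 1.52 ± 0.22 on the log2 scale (adjusted p = 0.510), its mean signal being -3.79 on normal sodium with AngII, against -2.47, -2.61 and -2.41 on normal sodium, low sodium and low sodium with AngII. Ccdc157 at 1.28 (0.79 after normexp) and the heparan sulfate sulfotransferase gene Hs3st5 at 1.07 followed upward, and Tuba3b at -1.15, the DNA methyltransferase gene Dnmt3a at -1.14 and Trim34 at -1.08 (-0.31 after normexp and -0.38 in the authors' values) downward. Postn stood at -1.08, but at -0.28 after normexp and -0.27 in the authors' values. Tgfb1 stood at -0.65, Col1a1 at -0.41, Ccn2 at -0.32, Ace at -0.19, Nppa at -0.14 ± 1.16, Acta1 at -0.10, Myh7 at -0.07, Agtr1a at 0.11, Myh6 at 0.20 and Timp1 at 0.23. Ccn2 turned to 0.15 without normal sodium with AngII replicate 2, and was -0.80 without replicate 3 of that group, -0.19 without low sodium with AngII replicate 2, -0.59 without normal sodium replicate 2 and -0.14 without normal sodium replicate 3. Tgfb1 was -0.39 without low sodium with AngII replicate 3 and -0.30 with array weights, and Col1a1 -0.25 without normal sodium replicate 1, -0.67 without normal sodium replicate 3 and -0.12 with array weights.

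The other 18 lists passed camera without the block in none of the 7 contrasts, with adjusted p of 0.0713 or more, and the values that follow are for the mean diet effect. Markers of fibroblasts (10 genes) had a mean of -0.16, lymphocytes (14) -0.19, adipocytes (5) -0.18, atria (12) 0.18, skeletal muscle (10) -0.06 and Schwann cells and neurons (9) -0.18, with adjusted p of 0.247, 0.143, 0.0924, 0.247, 0.652 and 0.329. TGF-beta signalling (22 genes) had a mean of -0.17, chemokines, cytokines and adhesion genes (23) -0.10, the renin-angiotensin system (12) -0.17, corticosteroid-responsive genes (18) 0.03 and the natriuretic peptide system (9) -0.38, with adjusted p of 0.0789, 0.287, 0.143, 0.342 and 0.0882. Adult contractile and calcium handling genes (19) had a mean of -0.02, fructose use and lipogenesis (15) 0.02, ion transport (24) 0.00, circadian clock genes (14) -0.04 and immediate early genes (23) 0.08, with adjusted p of 0.919, 0.728, 0.392, 0.832 and 0.652. Hypoxia response genes (14) had a mean of -0.04 and apoptosis genes (17) -0.10, with adjusted p of 0.652 and 0.0954.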

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

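The tests of the interferon response below (each array left out, slide 2 left out, and other assignments of the arrays) were chosen only after its interaction had been seen. In 6 gene lists the test of the difference between the AngII effects on low and normal sodium passed at the preset correlation, and none passed with an estimated one (adjusted p = 0.886 for each). Fatty acid oxidation genes differed by -0.21 on the log2 scale, smooth muscle and myofibroblast markers by -0.59, cholesterol synthesis genes by 0.20, cardiac stress and fetal genes by -0.45 and collagens and matrix proteins by -0.24.

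Interferon response genes differed most, by -0.81, with Irf7 at 1.05 for AngII on normal sodium and at -0.67 for AngII on low sodium. No 1 array accounts for this, since the sign and the call were kept in 12 of 12 fits without 1 array (-1.06 to -0.59). The 4 arrays of slide 2 are a candidate source: without them the difference was -0.24 (adjusted p = 0.194), while it was -0.88 without slide 1 and -1.27 without slide 3. Chance could not be excluded either. Of 200 assignments of the arrays 18, the real one included, gave a score difference as large (exact permutation, two-sided p = 0.09, and 0.1875 within slides). The real difference was -0.78, and another assignment gave one of 1.09 in size. Such assignments are exact only if AngII has no effect on either diet. An effect of salt intake on the interferon response to AngII stays open and is not separated from these by the 3 slides.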

How the results depend on the processing

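Leaving out slides and the permutations of list scores were chosen only after the list results had been seen. In every contrast 0 probes passed, so any count above 0 is a change. After normexp, 6 probes passed for AngII on normal sodium (4 higher, 2 lower), 3 for low sodium with AngII and 4 for the mean diet effect. Between diets with AngII, 1 passed after quantile normalisation, 4 after scaling to the median, 2 in the authors' values (5 for AngII on normal sodium), 2 among probes above background on all arrays (3 for AngII on normal sodium) and 1 with a random slide block. A variance trend with robust eBayes gave 8 for AngII on normal sodium, 4 for low sodium with AngII and 1 for the mean diet effect, which was also 1 without the filter on dim probes, where 14 lists passed. Array weights gave 8 probes between diets with AngII and 81 for the mean diet effect (15 higher, 66 lower), with 8 lists for AngII on normal sodium and 5 for its mean effect. With only the arrays of the groups compared, 2 probes passed for AngII on low sodium. An estimated inter-gene correlation left 0 lists in each of the 7 contrasts. Without slide 2 the interferon shift between diets without AngII was -0.12, the mean AngII shift of neutrophil and red cell markers -0.00468 and the cholesterol interaction -0.0696, each reversed. Leaving out 1 array gave 0 to 9 probes and 4 to 9 lists for AngII on normal sodium, 0 probes and 3 to 9 lists for AngII on low sodium, 0 to 1 and 2 to 15 between diets without AngII, and 0 to 3 and 6 to 12 with AngII. It gave 0 probes and 6 to 11 lists for the mean AngII effect, 0 to 20 and 6 to 12 for the mean diet effect (20 without normal sodium replicate 2), and 0 probes and 1 to 6 lists for the interaction (1 without low sodium replicate 2 or normal sodium with AngII replicate 1). Of the other 151 counts 124 stayed within 1.5 times the reported one, and of 700 list shifts 563 kept their sign and call, 134 lost the call and 3 reversed. Of 600 list shifts without 1 array 505 kept the call and 95 lost it. Postn, Lmod1 and Grid1 were smaller after normexp, which also used median intensities. The cause of these changes was not tested.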

Other observations

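The gene differences in the first 2 paragraphs and the tests of matrix and red cell genes were chosen only after the results had been seen, whereas the counts over other splits of the arrays were planned, except those within slides. In lists that did not pass camera without the block, single members changed between diets when adjusted over the list alone (mean diet effect, limma, 6 arrays against 6). Of these lists the natriuretic, fibroblast and adipocyte ones passed the exact permutation across slides, and the natriuretic one camera with the block. Of the natriuretic system the receptor gene Npr1 (log2 change -0.43), Nppb and Nppa fell while Corin, the protease that activates these peptides, rose (0.84). The cation channel gene Trpc6 fell (-0.51). Immune members that fell were Cd4 (-0.59) and the class II genes RT1-Da (-0.62) and RT1-DMa (-0.57). None of these passed when adjusted over all genes.

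Fibroblast activation protein (Fap, -0.66), the adipocyte gene Cfd (-0.47), the smooth muscle gene Mcam (-0.48), the vasodilator peptide gene Adm (-0.42) and the immediate early gene Klf6 (-0.40) also fell adjusted over their lists alone. Of apoptosis genes 4 fell, Bbc3 (-0.36), Casp12 (-0.34), Apaf1 (-0.31) and Bax (-0.26), and 0 of these with the block, as was the case for Mcam and Klf6. For AngII on normal sodium Ltbp2 of the TGF-beta signalling list (1.01) and the red cell genes Alas2 (1.53) and Hbb (0.71) rose over their lists alone. For the interaction Alas2 (-1.41) and Hbb (-0.70) were lower over the red cell list alone.

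The lower matrix list on low sodium may reflect less matrix expression per cell or fewer cells of some type. A lower share of all cells other than myocytes would lower smooth muscle markers alike, but the smooth muscle score stood 0.50 above the matrix score in the mean diet effect (exact permutation, two-sided p = 0.01, and 0.03125 within slides). This mean joins opposite directions. On low sodium the smooth muscle score rose without AngII (-0.33 to 0.06), 0.67 above the matrix shift (exact permutation, two-sided p = 0.1), and fell with AngII (0.23 to 0.04), 0.33 above it (exact permutation, two-sided p = 0.2). With 3 arrays a side neither part can pass alone, and within slides the exact permutation p of 0.03125 is the smallest possible. The values show only that the smooth muscle score did not follow the matrix score in the mean diet effect. A lower share of all these cells stays open, in infused rats and for that mean. A lower share of fibroblasts would lower fibroblast markers as far, and their score stood 0.24 above the matrix score (exact permutation, two-sided p = 0.03, but 0.0625 within slides), so this stays open. The shift kept its sign and call in 12 of 12 fits without 1 array (-0.44 to -0.36), and 1 of 200 assignments across slides, the real one, gave a score difference as large (real -0.40, largest other 0.38). With arrays exchanged only within slides the exact permutation p was 0.03125, the smallest possible, but 0.118 after adjustment over the 34 lists from which this one was picked, so 64 assignments are too few to exclude chance. Fewer endothelial cells or macrophages, whose markers fell too, and an effect of position on the slide, which cannot be told apart from group, stay open beside an effect of the diet.

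Red cell genes higher with AngII could come from residual blood or from probes that bind several haemoglobins. Neutrophil markers minus red cell genes gave -0.35 for the mean AngII effect (exact permutation, two-sided p = 0.34; 3 and 5 genes). On normal sodium red cell genes rose by 0.61 on average while neutrophil genes stood at -0.27, a difference of -0.88 (exact permutation, two-sided p = 0.4) that goes against residual blood on slides 2 and 3 (-1.38 and -1.74) but not on slide 1 (0.47). On low sodium the red cell and neutrophil means were -0.01 and 0.18, a difference of 0.19 (exact permutation, two-sided p = 0.5). With 3 arrays a side and so few genes, residual blood stays open. The 3 red cell genes that are no haemoglobin genes, Alas2, Slc4a1 and Ahsp, were higher by 0.36 on average (exact permutation, two-sided p = 0.275), which leaves binding between haemoglobin paralogs open. Hba-a1 stood at 0.07 and Slc4a1 at -0.13, both abundant in red cells. More immature red cells stay open and were not tested.

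Other splits of the arrays into groups of the same sizes show how often counts as large arise. With 10 splits per pair of groups the splits are too few for a share under 0.05. No probe passed the threshold in any contrast, so every split gave as many (10 of 10 for pairs of groups, 100 of 100 for the others) whatever the data, and these counts decide nothing on chance. For AngII on normal sodium 2 of 10 splits gave as many probes at an unadjusted p under 0.05 (real 1453, highest other 2043) and 4 as many lists (5, 7). For AngII on low sodium these were 10 (342, 1766) and 5 (5, 7), between diets without AngII 2 (1407, 1696) and 3 (7, 10), and with AngII 1 (2223, 1712) and 1 (10, 9). For the mean diet effect 4 of 100 splits gave as many probes at an unadjusted p under 0.05 (2508, highest other 3178). Within slides 1 of 32 did, the real one (highest other 2109). Both shares are under 0.05, but 1 of 32 is the smallest possible. Neither was adjusted for the several counts and contrasts compared, so they do not exclude chance for this count of the mean diet effect. Chance was not excluded for its lists (13 of 100; 9, 14; within slides 4 of 32). Nor was it for the mean AngII effect, with 77 of 100 for probes at an unadjusted p under 0.05 (576, 2735) and 17 for lists (8, 11). The interaction had 28 (1014, 3823) and 42 (6, 11), from splits that are exact only if AngII has no effect on either diet.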
